A study of Mus musculus with 6 samples.

How the data were processed

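Total RNA of embryonic mouse back skin was extracted with Trizol and RNeasy columns, biotin labelled and hybridised to Affymetrix MOE430 2.0 arrays, per the labels' protocols and the series design. All 6 arrays entered, 3 from Fzd6+/– (control) and 3 from Fzd6–/– embryos (knockout), grouped by the genotype in the labels. The deposited values are expression summaries made by RMA (background correction, quantile normalisation between arrays and summary over the probes of a set), per the submitters' processing notes, which name RMA without a version. The log base is not written in the sources used here. The deposited values run from 2.39 to 14.8 with medians of 5.99 to 6.03, as RMA values on the log2 scale do, and were read as log2. RMA forces the arrays to nearly the same distribution, so a shift of most genes in 1 direction would not show, and it pulls large fold changes of dim probe sets toward 0. Scanner files were not used here, so detection calls were not made and signal over background is known only from the level of each probe set.

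The table held 45101 rows, of which 64 array control probe sets (AFFX) were left out of all tests, and no filter on low values was applied to the remaining 45037. Names came from the platform's annotation, updated through Entrez identifiers to the gene table of GRCm38.p6. Of the tested probe sets 34945 had 1 gene symbol, 932 several and 9160 none, and 34741 matched the gene table. Only probe sets with 1 symbol were named. Where a value per gene was needed, the probe set with the highest mean over the 6 arrays was used, which gave 18194 genes. Probe sets of a gene can disagree. Others of the same gene are given for part of the named genes only, so a difference given for 1 probe set need not hold for the rest.

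Differences (knockout minus control, log2) were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates, prior degrees of freedom 3.43 beside 4 residual), with Benjamini-Hochberg adjustment over all 45037 probe sets, a threshold of adjusted p under 0.05 and 95% confidence intervals from the fit. Values are given as mean ± SD of 3 arrays. Gene lists for cell types and pathways of embryonic skin, 27 with 537 genes of which 501 were measured, were fixed before the data were examined. Of these, 26 were tested with limma's camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists, and the sex-linked list was only read per array. Camera with a correlation estimated per list and fry were alternatives. The preset correlation assumes that genes of a list vary almost independently between samples. In these lists the estimated correlation reached 0.835 (endothelium and pericyte) and was 0.474 for the suprabasal list, so calls at the preset value measure how a list stands out among genes on these arrays, more than how far it varies between embryos. Neighbours of Fzd6 were compared with Fisher's exact test, and single values with an exact permutation test, whose smallest two-sided p for 3 against 3 is 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

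Genes named in the text follow a rule fixed before the data were examined: Fzd6; genes past the adjusted threshold (there were none); failing that, up to 10 higher and 10 lower named genes with the largest differences at an unadjusted p under 0.001 and a mean above the median; 14 genes of polarity, hair follicle, Merkel cell and keratinocyte biology; the 3 members of each list with the smallest p; the sex-linked genes; and the 3 neighbours of Fzd6 with the smallest p. Any gene outside the rule is said to be chosen after its values were seen.

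The arrays of both groups carry replicate numbers 1 to 3. Deviations from the group means correlated at 0.568, 0.359 and 0.124 for arrays of the same number, all above 0.1, and by a criterion set before the fits were compared the numbers were taken to pair the samples. The labels do not say what a number stands for, and control 2 correlated more with knockout 3 (0.422) than with its own partner, so the pairing comes from the data alone. Deviations within a group sum to 0, so the 3 correlations are not separate evidence. The mean of Y-linked genes was 3.12 in control 2 and 7.88 in knockout 2. It was 7.93 in control 3 and 3.15 in knockout 3, so numbers 2 and 3 join unlike arrays in this respect. Values of the blocked fit stand beside each result whose call they change.

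The 3′ minus 5′ differences of the array's own Gapdh probe sets lay between −0.126 and 0.017 and those of beta-actin between 0.327 and 0.45, with no split by genotype. Alternatives tried were a prior variance with a trend, leaving out probe sets below the median, a further quantile normalisation, centring of each array, array weights, the replicate block, the Y-linked mean or the muscle list mean as a covariate, each array left out in turn, other thresholds, other probe set choices and other windows around Fzd6. For a value that passed no test in either setting, a change of sign was not counted as a reversal. The fit was tested on simulated data with independent errors and 200 of 45037 probe sets changed, all of them above the median level. It called 67 of 100 changed by 1 and 96 of 100 changed by 2 on the log2 scale, and 4 of 44837 unchanged ones. In the same kind of data, with independent genes, camera called a 20-gene list shifted by 0.5 and 0 of 25 others.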

Results

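RNA from mouse embryonic back skin, taken at E15.5, was measured on Affymetrix MOE430 2.0 arrays, on which each transcript is read by sets of short probes. The series compared 3 samples from embryos heterozygous for Fzd6 (Fzd6+/–, called control) with 3 samples from embryos lacking it (Fzd6–/–, called knockout), all on a mixed strain background. Fzd6 encodes Frizzled 6, a receptor of the Wnt family's Frizzled class that acts in planar cell polarity, the system that aligns hair follicles with the body axis. The labels call the samples biological replicates, and whether each came from 1 embryo, or which embryos were littermates, is not given in the sources used here. The values were RMA expression values on the log2 scale for 45037 probe sets, with array medians between 5.99 and 6.03. Their number, 3 per group, limits the precision of each difference.

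Correlations over probe sets between pairs of arrays lay between 0.986 and 0.996. No pair was a duplicate, since the SD of the difference between 2 arrays was 0.199 to 0.397. The leading principal component, with 48.3% of the variance, did not separate the genotypes. Knockout 1 lay at −48.4 and control 1 at −19.9 on it, and the other 4 arrays lay between 9.51 and 30.8. On the next component, with 20.7% of the variance, the groups did not overlap. Controls 1 to 3 lay at −30.35, −15.4 and 3.89 there and knockouts 1 to 3 at 12.0, 11.3 and 18.5. Control 3 thus lay nearer the knockouts than the other controls. For any 1 component, chance gives groups of 3 arrays without overlap in 10% of cases. The Y-linked genes Eif2s3y, Kdm5d and Uty averaged 3.12 in control 2 and 3.15 in knockout 3 against 7.88 to 8.39 in the other 4 arrays, so each group held 1 array of this kind. Xist, the RNA that silences an X chromosome in females, was in its brightest probe set at 13.3 in control 2 and 13.2 in knockout 3 and between 5.42 and 6.14 elsewhere, while its antisense transcript Tsix differed by 0.085 between the groups.

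The targeted gene was compared as a check of the labels. Fzd6 mRNA was read by 3 probe sets, and its values were lower in the knockout in 2 of them. The brightest measured 9.38 ± 0.23 in control and 8.93 ± 0.19 in knockout skin (log2, SD, n = 3), a difference of −0.44 (95% confidence interval −0.78 to −0.11, limma adjusted p = 0.909). In the dimmest the values were 6.13 ± 0.074 and 5.46 ± 0.089, a difference of −0.67 (−0.87 to −0.47, limma adjusted p = 0.864). The unadjusted limma p was 0.0165 in the brightest and 7.59e-05 in the dimmest. In each of the 2, all 3 knockout arrays lay below all 3 controls. The remaining probe set gave 6.10 in control and 6.09 in knockout, a difference of −0.0097 (−0.205 to 0.186). Neither the labels nor the tables used here place these probes relative to the deleted part of the gene. A probe outside that part need not show the loss. The brightest probe set still read 8.93 in knockout skin, above the array medians of 5.99 to 6.03. Signal thus remained in it without an intact gene, from a source that was not traced. The controls also carry 1 mutant copy, so the comparison is with a reduced dose, not with wild-type skin.

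**Figure D1:**
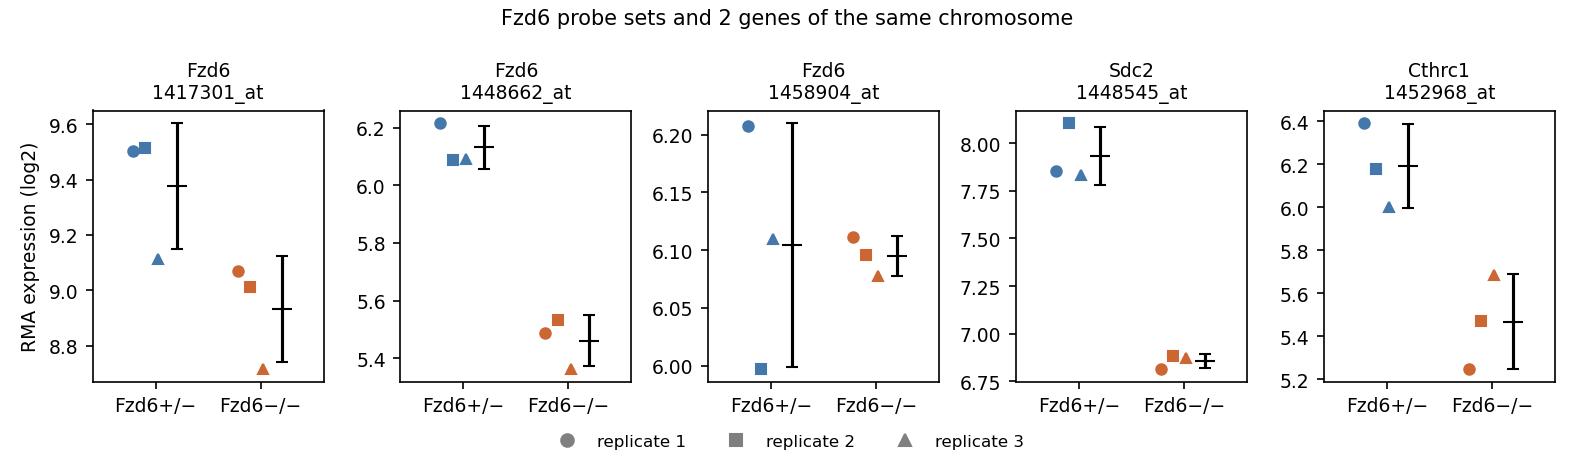
RMA expression (log2) of the 3 Fzd6 probe sets and of Sdc2 and Cthrc1, which lie on the same chromosome, in each Fzd6+/– and Fzd6–/– array. Symbols mark the replicate number, and bars give the group mean and SD (n = 3). The knockout arrays lie below all controls in the brightest and the dimmest Fzd6 probe set (means 6.13 and 5.46 in the latter), in Sdc2 and in Cthrc1. In the remaining Fzd6 probe set the group means are 6.10 and 6.09.

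The question of the genome-wide comparison was which transcripts differ in skin when Fzd6 is absent. No probe set passed limma's adjusted p of 0.05 over 45037 probe sets (smallest adjusted p = 0.295). At an unadjusted p under 0.05 there were 2348 probe sets, 1163 higher and 1185 lower in the knockout, where chance alone gives 2252. At an unadjusted p under 0.001 there were 20, of which 3 were higher and 17 lower, where chance gives 45. The values of the groups did not overlap in 5202 probe sets, 11.6% of all, where chance gives 10%. With the replicate number as a block, 3 probe sets passed, all lower in the knockout: 1 of Sdc2 (adjusted p = 0.0453 in limma) and 2 that carry no gene name here. These 2, chosen after their values were seen, differed by −1.64 (adjusted p = 0.0228 in the blocked limma fit) and −1.44 (adjusted p = 0.0453 there). In simulated data of the same size, limma called 67 of 100 probe sets changed by 1 on the log2 scale and 96 of 100 changed by 2. The changed probe sets were drawn only from those above the median level, and errors were independent between probe sets. Dimmer or fewer changed probe sets were not simulated, so these shares need not hold for the real arrays.

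The genes with the smallest unadjusted p and a level above the median did not pass the adjusted threshold and are given as values. Sdc2, a heparan sulfate proteoglycan of the cell surface, had the largest negative difference among them, from 7.93 ± 0.15 to 6.85 ± 0.038, or −1.08 (−1.30 to −0.85, limma adjusted p = 0.295). Its other probe sets differed by −0.58, −0.29 and −0.14. Has2, which makes hyaluronan, was at 6.50 ± 0.14 in control and 5.90 ± 0.036 in knockout (−0.60, −0.82 to −0.38), and its brighter probe set differed by −0.21 (−0.52 to 0.10). Cald1, an actin-binding protein, differed by −0.46 (−0.65 to −0.27), and its other probe sets by −0.27 (the brightest), −0.065 (also brighter), −0.097 and −0.24. The kinase Nek6 (−0.45), the secreted protein Fibin (−0.47), the chromatin remodeller Smarca1 (−0.39), the mitochondrial protein Ttc19 (−0.48) and Mapk1ip1l (−0.48) were the others with lower values. Brighter probe sets gave less for Ttc19 (−0.15, −0.51 to 0.22), Mapk1ip1l (−0.11, −0.43 to 0.22) and Nek6 (−0.38), and the dimmest of Nek6 gave −0.0060. On the positive side, Pnpla3, a lipid-droplet lipase, was at 6.59 ± 0.38 in control and 7.99 ± 0.44 in knockout (1.41, 0.81 to 2.00), and Slc6a4, the serotonin transporter, differed by 0.58 (0.32 to 0.83). Each of these genes had an adjusted p of 0.909 in limma except Sdc2.

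Whether the loss of Fzd6 was accompanied by shifts in other Frizzled receptors or polarity genes was examined in 2 fixed lists. Among 24 measured planar cell polarity genes, 8 had higher and 16 lower values, with a mean difference of −0.11, which did not pass the test (limma camera adjusted p = 0.0648). Fzd3, which overlaps with Fzd6 in function, differed by −0.21 (−0.50 to 0.085; dimmer probe sets −0.020 to 0.13), Celsr1, the atypical cadherin of the pathway, by 0.23 (−0.20 to 0.66), and Vangl2, its membrane partner, by −0.022 (−0.36 to 0.32). Astn2 differed by 0.11 (−0.089 to 0.31) at a level of 4.12 to 4.23, and its relative Astn1 by −0.32 (−0.66 to 0.029). The smallest p of the list belonged to Wdpcp (−0.25) and Intu (−0.21), planar polarity effectors of the cilium. Among the 15 other Frizzled receptors and co-receptors, 4 had higher and 11 lower values, with a mean of −0.10 (camera adjusted p = 0.102). The co-receptors Ryk (−0.28, −0.53 to −0.037) and Ror1 (−0.30) and the receptor Fzd5 (0.20, 0.020 to 0.39) had its smallest p, but a Ryk probe set of nearly the same level gave 0.0092 (−0.19 to 0.21) and a dimmer Ror1 probe set 0.26. With the replicate block both lists passed as lower, at adjusted p = 0.0121 and 0.0154, but at adjusted p = 0.67 for both with an estimated correlation. Leaving out single arrays moved both. Without control 1 they passed as lower at −0.203 and −0.205 (camera adjusted p = 0.00282 and 0.00212), without knockout 2 at −0.194 and −0.173 (0.00575 and 0.0174) and without knockout 3 at −0.143 and −0.147 (0.0419 and 0.0425), while without knockout 1 the means were −0.0031 and 0.010. The polarity list also passed with a variance trend (camera adjusted p = 0.0468), centred arrays (0.0404) and the Y-linked covariate (0.0289), and both lists did without replicate 1 of both groups (means −0.093 and −0.092, 0.0353 each). With all 6 arrays they had adjusted p = 0.777 and 0.834 with an estimated correlation. Both lists lay lowest in knockout 1 (−0.278 and −0.279), followed by control 1 (−0.123 and −0.152). Endothelial and fibroblast lists were lowest in the same arrays, at −0.838 and −0.464 in knockout 1 and −0.433 and −0.258 in control 1.

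Over all 26 lists tested, camera with its preset inter-gene correlation of 0.01 called 5, of which 4 were higher and 1 lower in the knockout. None was called with an estimated correlation (smallest adjusted p = 0.555 with an estimated correlation) or by fry (smallest adjusted p = 0.519). The count of called lists moved with the setting. It was 12 with the replicate block (5 higher, 7 lower; 0 with an estimated correlation) and 10 with each array centred on its median (4 higher, 6 lower). It was 13 without control 1, 8 without control 2, 13 without knockout 2 and 12 without knockout 3.

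**Figure D2:**
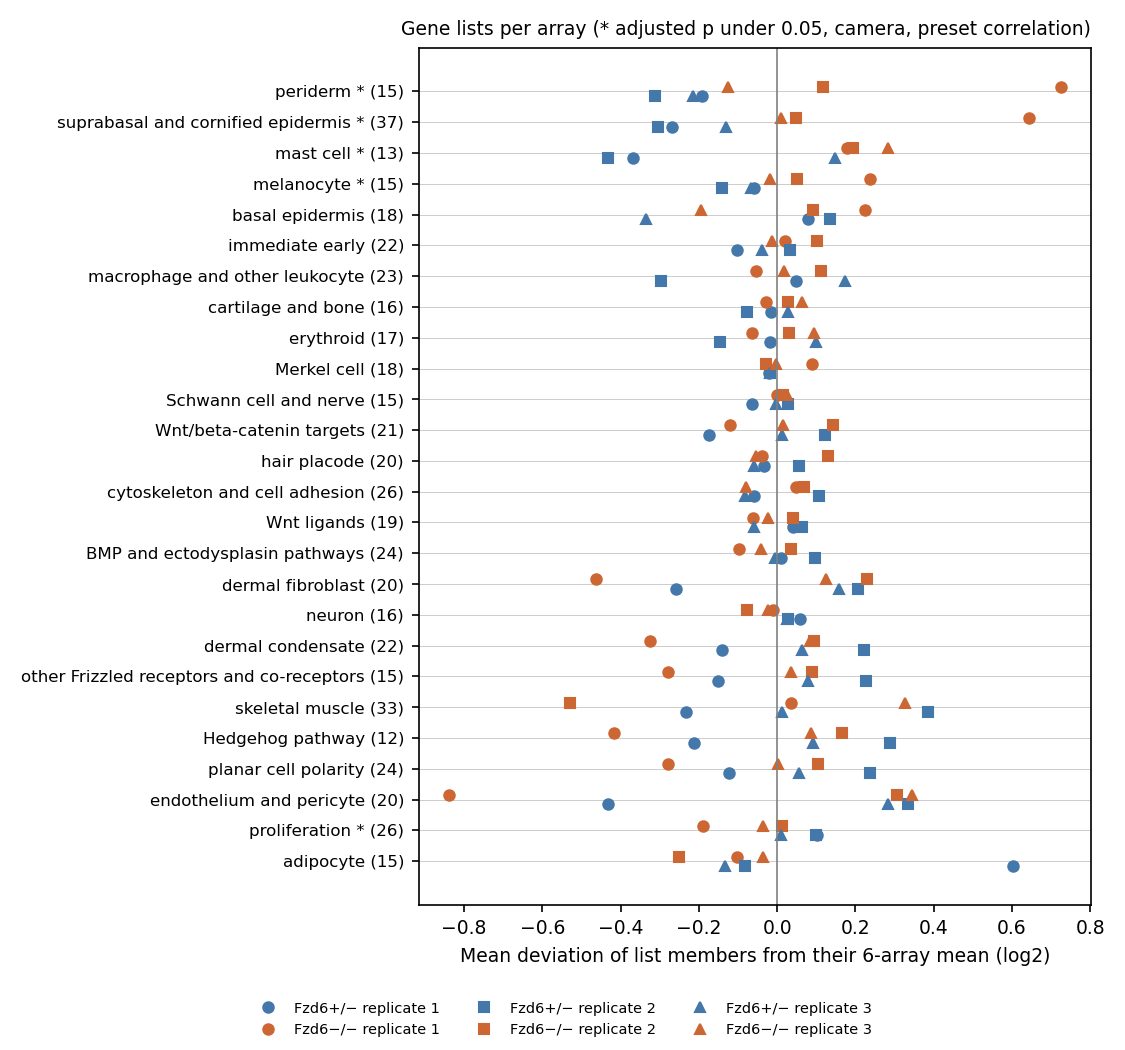
Mean deviation of each list's members from their own 6-array means (log2) in each array, with the number of measured genes in brackets; blue marks Fzd6+/–, orange Fzd6–/–, and the symbol the replicate. The suprabasal list lies at 0.64 in knockout 1 and at 0.049 and 0.0097 in the other knockout arrays, against −0.30 to −0.13 in the controls.

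Genes of the differentiating epidermis were higher in the knockout. Of 37 measured genes of the suprabasal and cornified epidermis, 35 had higher values, with a mean difference of 0.47 and a median of 0.31 (camera adjusted p = 1.43e-14). The call was lost with adjusted p = 0.555 with an estimated correlation. No member passed singly, and 0 members passed when adjusted over the list alone (smallest 0.058). Ivl, which encodes involucrin of the cornified envelope, was at 6.46 ± 0.21 in control and 7.49 ± 0.53 in knockout (1.02, 0.43 to 1.61), with 0.41 (−0.088 to 0.90) in its other probe set. Cnfn, or cornifelin, differed by 1.25 (0.48 to 2.01) and Sprr1a, a small proline-rich envelope protein, by 1.12 (0.41 to 1.83). The keratins of the spinous layer differed by less, with 0.32 for Krt1 (0.051 to 0.59) and 0.23 for Krt10 (0.015 to 0.44), both near the top of the array's range at 13.1 to 14.3. Knockout 1 contributed most, and without it the mean of the list was 0.26 (camera adjusted p = 1.43e-07, adjusted p = 0.93 with an estimated correlation). In knockout 1, where the list lay at 0.643, endothelial and fibroblast genes were at their lowest, at −0.838 and −0.464. In control 1 they were also low, at −0.433 and −0.258, with the suprabasal list at −0.268.

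The periderm, the flat outer cell layer of embryonic skin, gave 13 of 15 genes with higher values and a mean of 0.48 (camera adjusted p = 0.00101, but adjusted p = 0.777 with an estimated correlation). Adjusted over the list alone, 4 members passed: Krt13 (1.83, 0.80 to 2.87), Krt23 (0.98, 0.33 to 1.62), Sprr3 (1.35, 0.45 to 2.25) and Krt6a (1.09, 0.33 to 1.85), the last chosen after its value was seen, and over all probe sets none passed. Krt8, a keratin of simple epithelia, differed by 0.36 (−0.19 to 0.92). This list shares 2 genes with the suprabasal list, and without knockout 1 its call was lost (mean 0.235, camera adjusted p = 0.116), though not without both replicate 1 arrays (mean 0.259, camera adjusted p = 0.00779). The basal epidermis, the proliferating layer beneath, had 12 of 18 genes higher, with a mean of 0.081 (camera adjusted p = 0.573). Its keratins differed by 0.22 for Krt5 (−0.29 to 0.72), 0.31 for Krt14 (−0.30 to 0.91) and 0.30 for Krt15 (−0.018 to 0.62), and the binding protein Igfbp2 by −0.14. Within replicate numbers 1 to 3, examined after the data were seen, the keratin differences had the same sign, at 0.231, 0.147 and 0.27 for Krt5, 0.291, 0.28 and 0.346 for Krt14 and 0.331, 0.318 and 0.26 for Krt15, unlike Igfbp2 at −0.14, −0.337 and 0.059. The basal list passed as higher in the replicate block (adjusted p = 0.0404, but adjusted p = 0.731 with an estimated correlation), without control 2 (mean 0.169, camera adjusted p = 0.02) and without knockout 3 (mean 0.199, camera adjusted p = 0.0242), and its mean was −0.010 without knockout 1 and 0.050 without both replicate 1 arrays. With all 6 arrays it had adjusted p = 0.96 with an estimated correlation.

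**Figure D3:**
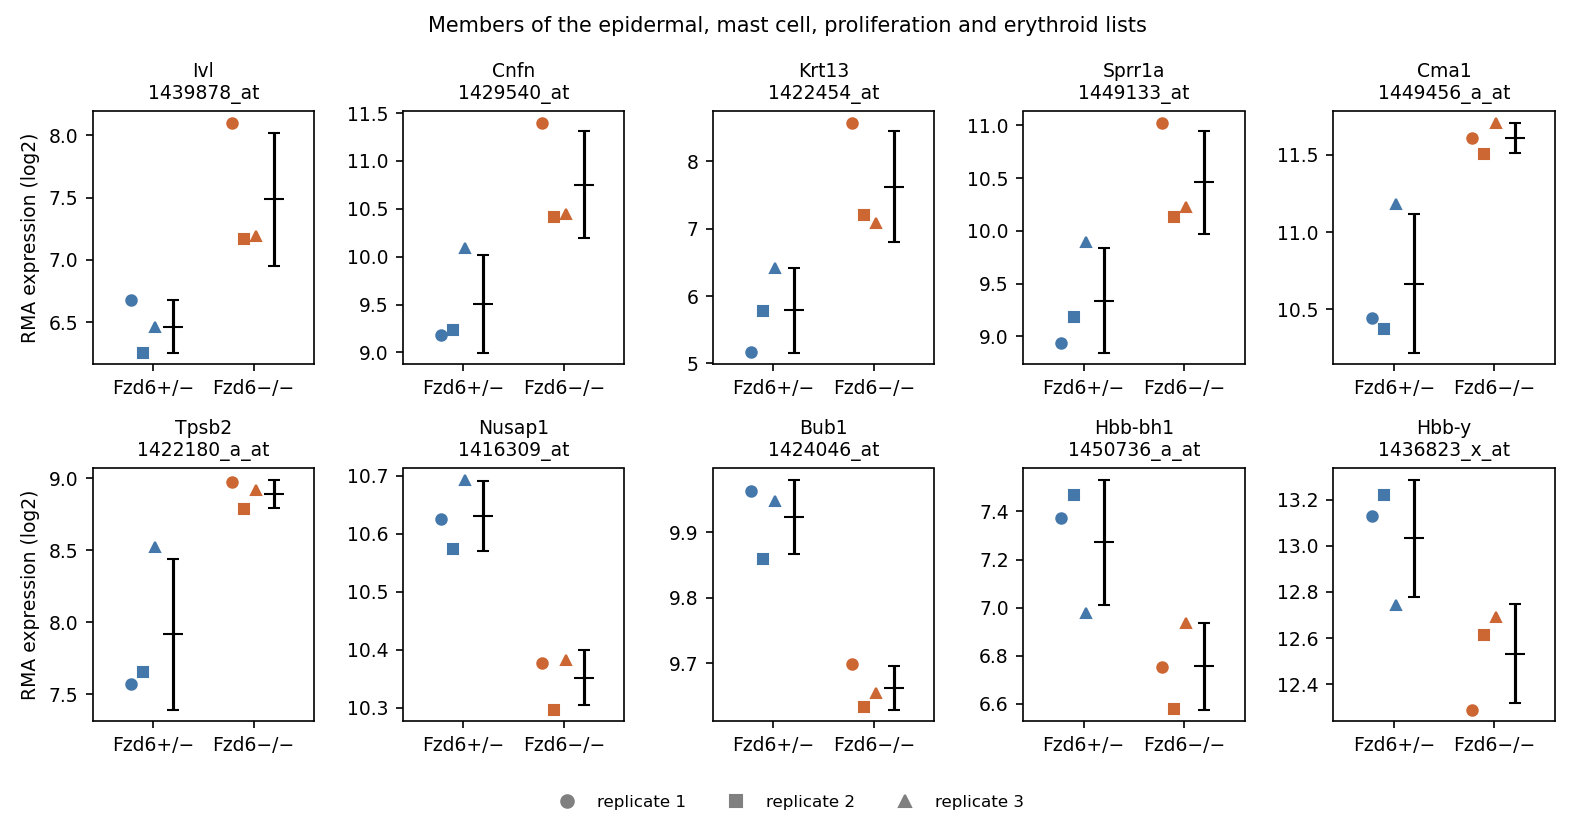
RMA expression (log2) of members of the epidermal (Ivl, Cnfn, Krt13, Sprr1a), mast cell (Cma1, Tpsb2), proliferation (Nusap1, Bub1) and erythroid (Hbb-bh1, Hbb-y) lists in each array, with group mean and SD (n = 3). Knockout 1 is the highest array for the 4 epidermal genes, and the 3 knockout arrays lie below the 3 controls for Nusap1 and Bub1, by −0.28 and −0.26 on average.

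Mast cell genes were higher in the knockout, in 12 of 13 measured genes, with a mean of 0.44 (camera adjusted p = 1.92e-07, but adjusted p = 0.555 with an estimated correlation). Cma1, the mast cell chymase, was at 10.7 ± 0.45 in control and 11.6 ± 0.098 in knockout (0.94, 0.46 to 1.42). The tryptases Tpsb2 (0.97, 0.42 to 1.53) and Tpsab1 (0.66, 0.27 to 1.05) moved alike, and 6 members passed when adjusted over the list alone (smallest 0.0204), though none over all probe sets. By array the list lay at −0.37, −0.43 and 0.15 in the controls and at 0.18, 0.19 and 0.28 in the knockouts. Macrophage and other leukocyte genes passed no test with all 6 arrays, with 10 of 23 higher and a mean of 0.050 against a median of −0.0056 (camera adjusted p = 0.865). That list passed as lower without control 2 (mean −0.0856, camera adjusted p = 0.000227) and as higher without control 3 (mean 0.15, camera adjusted p = 0.045), and with all 6 arrays it had adjusted p = 0.96 with an estimated correlation. Laptm5 (0.86, 0.097 to 1.63; its other probe sets −0.040 to 0.23), Itgam (0.20) and Fcer1g (0.18) had its smallest p.

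Melanocyte genes, those of the pigment cells then entering the follicles, had 14 of 15 members with higher values, at a mean of 0.18 (camera adjusted p = 0.0116, adjusted p = 0.555 with an estimated correlation). The pigment cell genes Gpr143 (0.22, 0.0072 to 0.44), Trpm1 (0.25, 0.00022 to 0.50) and Mlana (0.40, −0.041 to 0.84) had the smallest p, and 0 passed when adjusted over the list alone. The call was lost without knockout 1 (mean 0.10, camera adjusted p = 0.228) and with array weights (mean 0.125, camera adjusted p = 0.0974), and kept without both replicate 1 arrays (mean 0.119, camera adjusted p = 0.0465).

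Genes of cell division were lower in the knockout in all 26 measured members, by a mean of −0.14 (camera adjusted p = 1.92e-07, but adjusted p = 0.555 with an estimated correlation). The mitotic genes Nusap1, at 10.6 ± 0.060 and 10.4 ± 0.048 (−0.28, −0.46 to −0.098), and Bub1 (−0.26, −0.44 to −0.085) and the replication licensing factor Mcm6 (−0.25, −0.45 to −0.045) led the list. A dimmer Nusap1 probe set, at 6.09 and 6.22, differed in the other direction, by 0.13 (−0.11 to 0.36). No member passed when adjusted over the list alone (smallest 0.125). By array the list lay at 0.10, 0.099 and 0.011 in the controls and at −0.19, 0.013 and −0.037 in the knockouts. The groups thus overlapped, with knockout 2 above control 3 (exact permutation p = 0.2). Knockout 1 lay lowest, at −0.19, and without it the mean was −0.083 (camera adjusted p = 0.00609, but adjusted p = 0.93 with an estimated correlation). Without both replicate 1 arrays it was −0.067 (camera adjusted p = 0.0308).

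Hair follicle formation was under way at this stage, and the calls of some of its lists depended on the setting. The hair placode list had 11 of 20 genes higher, at a mean of 0.025 (camera adjusted p = 0.957). Shh, the morphogen of the placode, differed by 0.00094 (−0.31 to 0.32), the ectodysplasin receptor Edar by 0.12 (−0.25 to 0.49), the transcription factor Lhx2 by 0.68 (0.29 to 1.08), Bmp2 by 0.21 (0.0014 to 0.43) and the ligand Wnt10b by −0.18. Wnt/beta-catenin targets had 10 of 21 higher, with a mean of 0.025 against a median of −0.0090 (camera adjusted p = 0.865). Lef1, a nuclear partner of beta-catenin, differed by 0.0020 (−0.42 to 0.42), Axin2, the feedback inhibitor, by 0.12 (−0.36 to 0.60), and Bambi, Msx1 and Sp6 by 0.86, 0.22 and 0.32. Among the Wnt ligands 10 of 19 were higher, with a mean of −0.030 and a median of 0.00069 (camera adjusted p = 0.865), and Wnt16 (0.25), Wnt11 (−0.39) and Wnt8b (0.18) had the smallest p. Of the BMP and ectodysplasin genes 18 of 24 were lower, at a mean of −0.069 (camera adjusted p = 0.0648), with the BMP antagonist Grem1 at −0.41 (−0.68 to −0.15) and the ligand Eda at −0.19. This list passed as lower with a variance trend (camera adjusted p = 0.0468), centred arrays (0.041), without control 1 (0.0187), without control 3 (0.0461) and without knockout 2 (mean −0.104, 0.0116), and its mean was −0.037 without knockout 1 and −0.049 without both replicate 1 arrays. With all 6 arrays it had adjusted p = 0.555 with an estimated correlation.

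The dermal condensate, the mesenchymal partner of the placode, had 16 of 22 genes lower, at a mean of −0.098 (camera adjusted p = 0.0648). Sox2, one of its transcription factors, differed by −0.18 (−0.55 to 0.19), Cdkn1a by 0.25, Hhip by −0.22 and Tbx18 by −0.38. Hedgehog pathway genes were lower in 8 of 12, at a mean of −0.11 (camera adjusted p = 0.0648), with Smo at −0.24 and Cdon at −0.26. Both lists passed as lower with the replicate block, at adjusted p = 0.0259 and 0.00983, and neither did so with an estimated correlation (adjusted p = 0.67 and 0.707). Both also passed as lower with centred arrays (camera adjusted p = 0.0404 each) and the Y-linked covariate (0.0418 each), and the condensate list with a variance trend (0.0468). Without control 1 they passed at −0.193 and −0.245 (camera adjusted p = 0.00148 and 0.000833), without knockout 2 at −0.17 and −0.222 (0.00575 and 0.00517) and without knockout 3 at −0.165 and −0.181 (0.0127 and 0.0178), while without knockout 1 the means were 0.040 and 0.071 and without both replicate 1 arrays −0.054 and −0.063 (camera adjusted p = 0.329 and 0.16). With all 6 arrays they had adjusted p = 0.822 and 0.856 with an estimated correlation. The condensate and Hedgehog lists lay lowest in knockout 1 (−0.326 and −0.418), followed by control 1 (−0.14 and −0.213). Endothelial (−0.838 and −0.433) and fibroblast lists (−0.464 and −0.258) were also lowest in knockout 1 and control 1. Merkel cell genes, those of the touch-sensing epidermal cells, had 11 of 18 higher, at a mean of 0.038 (camera adjusted p = 0.463). Atoh1, the factor that specifies Merkel cells, differed by 0.14 (−0.073 to 0.35), and Gfi1, Insm1 and Chga by 0.32, 0.19 and 0.27.

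Markers of the other tissues that a piece of back skin could hold were followed per array. Skeletal muscle genes had 25 of 33 lower, at a mean of −0.11 (camera adjusted p = 0.0648), and lay at −0.53 in knockout 2 and at 0.39 in control 2; the muscle genes Myh7 (−0.34), Pax7 (−0.35) and Ttn (−0.41) had the smallest p. Endothelial and pericyte genes lay at −0.84 in knockout 1 and −0.43 in control 1 and between 0.284 and 0.345 in the other arrays. Their mean was −0.12 (17 of 20 lower, camera adjusted p = 0.2), with Pecam1 at −0.32, Tek at −0.18 and Emcn at 0.19. Dermal fibroblast genes showed the same pair of arrays low, at −0.46 and −0.26, with a mean of −0.072 (13 of 20 lower, camera adjusted p = 0.292) and Pdgfra, Crabp1 and Vim at −0.32, −0.21 and −0.18. In the replicate block the endothelial and fibroblast lists passed as lower, at adjusted p = 0.0121 and 0.0404, both at adjusted p = 0.731 with an estimated correlation. The endothelial list passed as lower without control 1 (mean −0.372, camera adjusted p = 0.000821), knockout 2 (−0.309, 0.0063) or knockout 3 (−0.328, 0.00203) and as higher without knockout 1 (mean 0.26, camera adjusted p = 0.00609), but had adjusted p = 0.96 with an estimated correlation (all 6 arrays) and 0.93 without knockout 1. Dropping knockout 1 alone leaves control 1, its partner by number, which was also low, and without both the mean was 0.016 (camera adjusted p = 0.9). The fibroblast list passed as lower without control 1 (mean −0.219, camera adjusted p = 0.00857) or knockout 2 (−0.205, 0.011) and had a mean of 0.142 without knockout 1, −0.0049 without both replicate 1 arrays, and adjusted p = 0.96 with an estimated correlation. The muscle list passed as lower without control 1 (mean −0.254, camera adjusted p = 0.000193), knockout 1 (−0.155, 0.0355) or knockout 3 (−0.301, 6.24e-07), without replicate 1 of both groups (−0.299, 2.6e-05), with a variance trend (0.0468), centred arrays (0.0404) and the Y-linked covariate (0.00676). It passed as higher without knockout 2 (mean 0.13, camera adjusted p = 0.0068), and had adjusted p = 0.96 with an estimated correlation (all 6 arrays) and 0.93 without knockout 1.

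Adipocyte genes stood apart in control 1, at 0.60 against −0.25 to −0.035 elsewhere, with a list mean of −0.26 (9 of 15 lower, camera adjusted p = 0.325) and Car3 at 9.71 ± 2.46 and 8.05 ± 0.93, Fabp4 at −0.63 and Ucp1 at 0.20. Neuron genes had 12 of 16 lower, at a mean of −0.075 (camera adjusted p = 0.102), led by the neurofilament gene Nefl (−0.56, −0.96 to −0.16), with Elavl3 at 0.17 and Elavl4 at −0.13. Schwann cell and nerve genes had a mean of 0.028 while the test pointed down (8 of 15 higher, camera adjusted p = 0.865), and Pou3f1, which keratinocytes also express, differed by 0.97 (0.39 to 1.55), Egfl8 by 0.15 and Fabp7 by −0.27. Cartilage and bone genes (8 of 16 higher, mean 0.042, camera adjusted p = 0.487) included Ucma at 0.30, Snorc at 0.17 and Acan at 0.21. Immediate early genes (15 of 22 higher, mean 0.072, camera adjusted p = 0.244) included Klf4 at 0.36, Fosl1 at 0.22 and Egr2 at 0.22, and passed as higher only without control 2 (mean 0.106, camera adjusted p = 0.0456; with all 6 arrays adjusted p = 0.813 with an estimated correlation). Cytoskeleton and cell adhesion genes (15 of 26 higher, mean 0.023, camera adjusted p = 0.865) included Pkp1 at 0.30, Jup at 0.24 and Rac1 at −0.24, with −0.058 in a Rac1 probe set of nearly the same level. Erythroid genes had 12 of 17 higher, at a mean of 0.041 (camera adjusted p = 0.865). Within them the embryonic beta-like globins Hbb-bh1 (−0.52, −0.87 to −0.16) and Hbb-y (−0.50, −0.87 to −0.13) had lower values and Hbb-b2 a higher one (0.88, −0.051 to 1.82), with −0.028 in its other probe set.

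Genes that neighbour Fzd6 were compared because the mutant allele can carry linked sequence of 1 parental strain into the knockout group. Gene order was taken from the GRCm38.p6 assembly, in which Fzd6 lies on chromosome 15, and no coordinates are given because the build behind the array annotation is not given in the sources used here. Within 100 genes on either side, 1 of 51 measured genes had an unadjusted p under 0.01 against 125 of 18142 elsewhere, an odds ratio of 2.88 (0.071 to 17.1, Fisher's exact p = 0.299, two-sided). That gene was Cthrc1, a secreted protein of the matrix that has been tied to Wnt signalling, at 6.19 ± 0.20 and 5.47 ± 0.22 (−0.72, −1.06 to −0.39), 3 genes from Fzd6. Slc25a32, a mitochondrial carrier 4 genes away, differed by −0.49 (dimmer probe sets −0.34 and 0.057), and the transcription factor Osr2 by −0.66, though a dimmer Osr2 probe set differed by 0.24 (0.054 to 0.43). Of the genes near Fzd6, 51% had the higher value in the knockout, and of all genes 52.4%.

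Over the whole of chromosome 15, a comparison added after the data were seen, 5 of 1370 probe sets had an unadjusted p under 0.001, Fzd6 left out, against 9 of 33572 other named probe sets. The odds ratio was 13.7 (3.59 to 45.4, Fisher's exact p = 0.000137, two-sided). The 5 were 2 of Sdc2 and 1 each of Has2, Pnpla3 and Serhl, a serine hydrolase-like gene chosen after its values were seen (−0.60, −0.81 to −0.39, its other probe sets at −0.24, 0.19 and 0.18). Fisher's test takes probe sets as independent, although 2 are of Sdc2. The test near Fzd6 used 1 probe set per gene, the brightest. In the brightest probe sets of Sdc2, Has2 and Serhl the unadjusted limma p was 0.0985, 0.159 and 0.0238. By that rule they would not count, so the excess depends on the choice of unit. For Sdc2 the rule rested on a near tie. Its brightest probe set had a mean of 7.397 over the 6 arrays, and the probe set that differed by −1.08 had 7.394. In the controls alone the latter was the brighter, at 7.93 against 7.54. At an unadjusted p under 0.01 the shares were 1.31% and 0.84%, an odds ratio of 1.57 (0.92 to 2.54, Fisher's exact p = 0.0712). Without knockout 1 the ratio at the stricter level was 1.86 (Fisher's exact p = 0.15). With any other single array left out, and in the replicate block, Fisher's exact p stayed under 0.05 at that level. These fits share arrays and are not separate evidence.

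**Figure D4:**
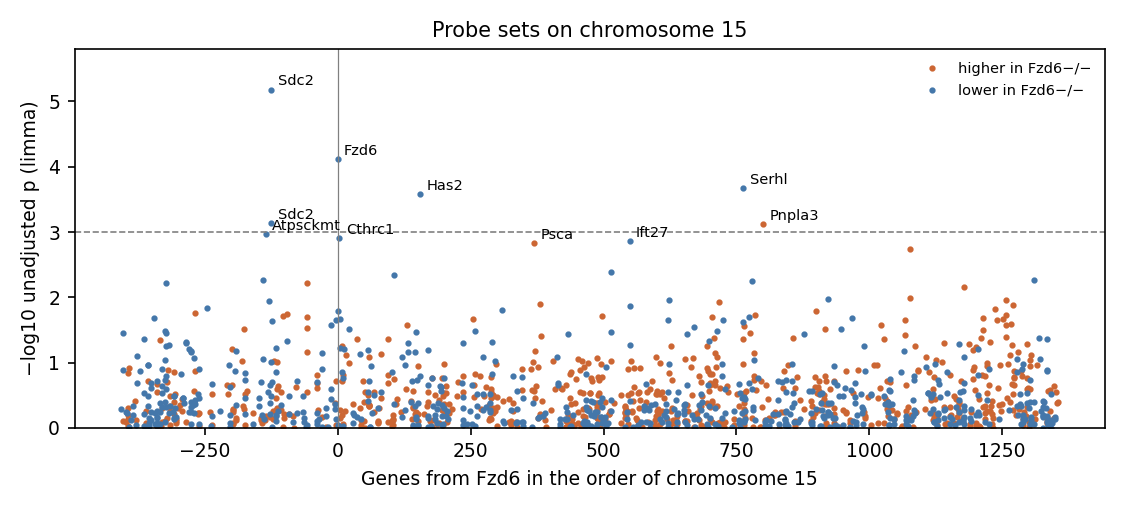
Probe sets on chromosome 15 by their place in the order of genes from Fzd6 (x axis, number of genes) and −log10 of the unadjusted limma p (y axis), orange where higher and blue where lower in the knockout. The dashed line marks p of 0.001, and 2 Sdc2 probe sets, 1 each of Has2, Serhl and Pnpla3, and 1 of Fzd6 lie above it.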

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

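Alternatives added after the data were seen were those without replicate 1 of both groups, the estimated correlation without knockout 1 and the chromosome-wide comparison. Calls among probe sets stayed at 0 in all settings except the replicate block, where 3 passed in limma. Of the values of named genes in alternatives 1615 stayed, none reversed, 7 moved by more than the spread, all without replicate 1 of both groups, and 1 (Sdc2, paired by replicate block) passed. These counts were largely fixed in advance and say little about stability. Leaving out 1 array cannot move a difference by more than that spread. The variance trend, the filter on dim probe sets and the replicate block leave the differences unchanged. The Fzd6 difference lay between −0.58 and −0.34 with each array left out, and depended on the probe set, at −0.67 in the dimmest and −0.0097 in another. The count of called lists, 5, was 9 with a variance trend, 10 with centred arrays, 12 with the replicate block, 9 with the Y-linked covariate, 8 without replicate 1 of both groups, 5 to 13 with each array left out, and 0 with an estimated correlation, with or without knockout 1, and with fry. The cause of these shifts was not tested. Suprabasal, mast cell and proliferation lists kept their call in 16 of 16 settings with the preset correlation, with means of 0.25 to 0.58, 0.33 to 0.62 and −0.185 to −0.067. Periderm lost it without knockout 1, melanocyte there and with array weights. Over all lists 421 values stayed, 50 gained a call, 18 lost one and 3 reversed, each on leaving out 1 array. The macrophage list ranged from −0.086 (without control 2) to 0.15, the endothelial list from −0.37 to 0.26 (without knockout 1) and the muscle list from −0.30 to 0.13 (without knockout 2). The odds ratio of the Fzd6 neighbours was 2.31 to 8.22 with each array left out, 1.41 in the replicate block, 5.55 and 2.41 in windows of 50 and 200 genes, 1.17 at p under 0.05, none past the threshold, and 13.7 for the whole chromosome at p under 0.001 (4.52 in the block). The replicate block changed no call beyond those given with the results. Signal over background was not available, so differences in dim probe sets are bounded by it to an unknown degree.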

Other observations

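Tests of the suprabasal list without knockout 1 and against the basal list (within replicate numbers too), of the genes near Fzd6 as an explanation, of the rest of chromosome 15, and of that chromosome over the splits were chosen only after the results were seen; the globin test and the other splits were written before.

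Among named probe sets, 26 of the 30 with the largest fold changes were higher in the knockout, and 26 had their highest value in knockout 1. No test was made of which kinds of gene these were, and the following 4 were chosen after their values were seen. Lce3f, a late cornified envelope gene, was at 6.67, 7.58 and 9.90 in controls 1 to 3 and at 12.1, 10.4 and 10.7 in the knockouts. Hrnr, or hornerin, was at 9.09, 8.78 and 10.2 against 12.4, 10.6 and 10.6. Gpx3, a secreted glutathione peroxidase, was at 8.20, 8.91 and 11.7 against 12.9, 12.2 and 12.1, and Krtap13, a keratin-associated protein, at 4.75, 4.66 and 5.43 against 10.9, 5.85 and 7.14. In each of these genes control 3 was the control closest to the knockouts.

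Some probe sets split the arrays without regard to genotype, again chosen after their values were seen. Adipoq, the fat cell hormone adiponectin, was at 8.64 in control 1 and 3.32 to 3.48 in the other 5 arrays. Afp, made by yolk sac and fetal liver, was in 1 of its 5 probe sets at 5.87 in knockout 1 and at 2.91 to 3.42 elsewhere. Knockout 1 was also the highest array, by less, in the Afp probe sets where it read 5.47, 4.19 and 3.83. It was not the highest in the probe set where it read 3.99. A probe set of Phgdh was at 5.98 and 5.42 in control 1 and knockout 2 and between 10.9 and 11.8 in the others. Another Phgdh probe set was between 10.2 and 10.8 in all arrays. A probe set of Rps9 was at 7.60 in control 2, 7.79 in knockout 2 and 8.05 in knockout 3 and between 12.6 and 13.1 in the other 3 arrays, while another Rps9 probe set was between 13.9 and 14.0 in all arrays.

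The higher level of suprabasal and cornified genes in the knockout may reflect more than 1 cause. Without knockout 1 the list means still differed by 0.263, over 2 times the within-group SD of 0.0763. The remaining knockout arrays, at 0.049 and 0.0097, lay above the controls. That rule was set after the result, and leaving out knockout 1 also shrinks the SD, which was 0.355 among the knockouts with it. Camera with an estimated correlation gave adjusted p = 0.93 without that array. Knockout 1 was therefore not the whole of the measured difference, but whether the rest exceeds the variation between embryos stays open. More epidermis in the knockout samples is a candidate explanation that stays open, because suprabasal minus basal values differed by 0.387 against an SD of 0.295 (exact permutation p = 0.3), and within replicate numbers 1 to 3 by 0.766, 0.395 and −0.0012; endothelial and fibroblast lists were lowest in knockout 1 (−0.838 and −0.464), as a smaller dermal share would give, but were low in control 1 too (−0.433 and −0.258), where the suprabasal list was not raised (−0.268). Older embryos in the knockout group also stay open. Embryonic globins (Hbb-bh1, Hbb-y, Hba-x) minus other erythroid genes (Hba-a1, Alas2, Slc4a1) differed by −0.838, in the direction that age predicts. The Hba-a1 probe set was dim, at 4.36 to 4.57 in all arrays, and differed by 0.0048. Change on that side came from Alas2 (0.53) and Slc4a1 (0.37), so the contrast is not one of embryonic against adult globins. In order of replicate number it lay at 3.31, 4.01 and 2.60 in the controls and at 2.38, 2.52 and 2.51 in the knockouts, lower within each number. The difference is under 2 times the unpaired SD of 0.501, and its exact permutation p of 0.1 is the smallest this design allows. Age and an effect of Fzd6 on differentiation thus cannot be told apart here.

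On chromosome 15 the excess of probe sets at an unadjusted p under 0.001 may come from sequence linked to the mutant allele, either through strain variants under probes or through linked regulatory variants. The test within 100 genes of Fzd6 gave an odds ratio of 2.88 (Fisher's exact p = 0.299). It could not bear on the excess itself, since Sdc2, Has2, Serhl and Pnpla3 lie outside that window. In the gene order they are at −125, 155, 763 and 801 from Fzd6. With the probe sets under 0.001 left out, the rest of the chromosome held 13 of 1365 at p under 0.01 against 273 of 33563, an odds ratio of 1.17 (0.62 to 2.05, Fisher's exact p = 0.539), so neither test decides. The comparison was 1 of several windows and levels tried, and of 10 splits of the arrays 1, the real one, gave as many as 5 such probe sets, the highest other giving 2; 10 splits are too few for a share under 0.05. An effect of Fzd6 on Sdc2 or Has2 themselves stays open and was not tested, and the unequal differences among probe sets of Sdc2, Has2 and Serhl were not traced to probe sequences.

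For the other results the 10 splits are likewise too few for a share under 0.05. The real split called 0 probe sets, which all 10 splits must equal or exceed, so this count tells nothing about chance; the highest other gave 3. As many lists as the 5 of the real split were called in 9 of 10 splits, the highest other calling 12. An odds ratio near Fzd6 as high as 2.88 appeared in 2 of 10, the highest other being 72.2. Of the 4 splits that part all 3 replicate pairs, the real one called 0 probe sets and 5 lists and the others 1, 0 and 0 probe sets and 9, 5 and 3 lists. Calling 5 or more lists was thus usual for splits of these arrays, which points to a structure of the samples that the preset correlation does not cover.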
